A study of Rattus norvegicus with 30 samples.

How the data were processed

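Liver RNA of male rats was measured on 30 spotted oligonucleotide arrays with 2 dyes, each holding the RNA of 1 rat in Cy5 and of another rat in Cy3. The labels give 20 rats in 4 groups of 5. Rats ate a diet with endophyte-free (E-) or endophyte-infected (E+) fescue seed and stayed at thermoneutrality (TN, 21°C) for 26 days or spent 5 days there followed by 21 days of heat (HS, 32°C). Endophyte-infected seed carries a fungus whose ergot alkaloids cause fescue toxicosis. Per the labels, 24 rats were studied and 12 were picked for arrays by their sensitivity to fescue toxicosis, whereas the array labels name 20 different rats, so how those 20 were picked is not given in the sources used here. Each rat was on 3 arrays. The arrays form a loop: E+TN in Cy5 with E-TN in Cy3 (8 arrays), E-HS in Cy5 with E+TN in Cy3 (7), E+HS in Cy5 with E-HS in Cy3 (8) and E-TN in Cy5 with E+HS in Cy3 (7). Each pairing has 1 dye orientation, and no array sets heated and unheated rats of the same diet side by side, so the heat effects rest on indirect paths through the loop. The loop has 2 parts of 10 rats that only 2 arrays join, rat 12 with rat 25 and rat 24 with rat 35. Within each part, both diets have equal numbers of rats at each temperature, but 6 rats of the first part and 4 of the second were heated.

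The deposited values are log2 ratios of the 2 dyes for each spot. No source used here states the scanner software or any normalization. The scale was read from the values: as linear ratios they fall on whole multiples of 0.001, and 679 of the 807330 values sit at 16.61, the log2 of a ratio of 100000. These ceiling values were left out, and 29178 values were missing. The deposited values were not centred between arrays. The median log2 ratios of the E+TN (Cy5) with E-TN (Cy3) arrays, replicates 1 to 8, were -0.628, -0.610, -0.413, -0.440, -1.047, -1.290, -0.669 and -0.660. Those of the E-HS with E+TN arrays, replicates 1 to 7, were -0.813, -0.546, -1.556, -1.283, -1.377, -0.697 and -0.908. Those of the E+HS with E-HS arrays, replicates 1 to 8, were 0.477, -0.786, -0.816, -0.131, 0.116, -1.478, -1.188 and -0.788. Those of the E-TN with E+HS arrays, replicates 1 to 7, were -0.834, 0.064, -1.415, -1.713, -0.969, -1.026 and -0.552.

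The direction of the ratio is not stated. It was taken as Cy5 over Cy3, the usual order of scanner software and the order of the channels in the labels, which makes this direction likely but not settled. Every sign below is conditional on it, and a ratio of Cy3 over Cy5 would turn each one. Over all probes, pairs of arrays correlated between r = -0.565 and r = 0.761. Of these arrays, 2 correlated below 0 on average with the others, namely E+HS rat 35 in Cy5 with E-HS rat 15 in Cy3 (mean r = -0.180) and E-TN rat 24 in Cy5 with E+HS rat 35 in Cy3 (mean r = -0.137). Their direction is therefore unsettled, and each comparison was repeated with their sign turned.

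The table has 26911 probes, of which 20490 have 1 gene symbol in the platform annotation, 58 have several and 6363 have none. The symbols are partly those of the mouse. None of the annotation's accessions or Entrez numbers matched the rat RefSeq table used here, so genes were named by symbol: 14705 of the 17026 distinct symbols are current rat symbols, and 386 were updated through a rat synonym. Genes such as Olfr25 are given under the name of the annotation. Probes of 1 symbol were averaged per array as log2 ratios; probes with several symbols or none were tested on their own. A gene or probe was kept with a value on at least 24 of the 30 arrays and from at least 4 of the 5 rats in each group. This left 22367, of which 16371 have a symbol and 5996 do not, and 17630 have a value on all 30 arrays. Among the values given for named genes, 13 are means of several probes; in 4 of these the probes had both signs, never both at an unadjusted p under 0.05. The number of arrays limits the precision: the median standard error over all genes was 0.105 for diet averaged over temperature, 0.145 for heat averaged over diet and 0.273 for their interaction (log2).

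Each array was centred on its median. For each gene, generalised least squares in R 4.3.3 with limma 3.58.1 fitted a gene-specific dye effect and the group of the Cy5 rat minus the group of the Cy3 rat, with rats as random effects through a common correlation of arrays that share a rat (0.08, the value with the highest summed restricted likelihood). Variances were moderated (prior degrees of freedom 3.29) and tests were two-sided, with Benjamini-Hochberg adjustment over all 22367 genes and a threshold of 0.05. The dye effect passed it in 8380 genes. There were 7 comparisons: diet at each temperature, heat on each diet, both effects averaged, and the interaction. In these, errors given as ± are standard errors of the log2 fold change unless called SD, and the number of rats in the direction of a change is that of treated rats lying beyond the mean of the untreated rats. With 200 genes changed in simulated data, the diet average recovered 71 of 100 genes changed by a log2 of 0.5 and 93 of 100 changed by 1, with 16 false calls. The heat average recovered 33 and 80 with 3 false calls, and the interaction 4 and 42 with 4 false calls, each over 22367 genes. Genes were simulated as independent, without the structure that the real arrays share, so these counts may be optimistic.

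The design, the groups, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. For the averaged effects and the interaction, the rule names the 8 genes with the largest rise and the 8 with the largest fall among genes with a symbol past the threshold, and the member of each list with the smallest p. For the other comparisons it names the 5 largest in each direction. With fewer than 5 such genes it adds the 5 with the smallest p, as values. A fixed panel of stress, cytochrome and metabolic genes was always given; of it, Cyp2b2, Cyp3a2, Cyp2c11 and Sod1 were not measured under those names or did not pass the filter. The 30 lists cover phase I metabolism, phase II conjugation, hepatic transporters, antioxidant defence, cytosolic chaperones, endoplasmic reticulum stress, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, bile acid synthesis, glucose production and glycogen, amino acid breakdown and the urea cycle, oxidative phosphorylation, the acute phase, complement and coagulation, growth hormone and sex-dependent genes, thyroid response, the circadian clock, ribosomal proteins, the proteasome, the cell cycle, apoptosis and DNA damage. Marker lists cover hepatocytes, macrophages and Kupffer cells, lymphocytes and neutrophils, stellate cells and fibroblasts, endothelium, biliary cells, red blood cells, and adipose, pancreas and muscle as neighbouring tissue. Lists were tested against all other genes with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison. In 10 simulated sets of arrays without any effect it called 0 lists, but genes were simulated as independent, and regrouping the real rats called a median of 1 list for diet averaged, 3 for heat averaged and 4 for the interaction. Camera with an estimated correlation and fry were alternatives.

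Other alternatives were no centring, scaling to a common spread, 2 other filters on missing values, each probe on its own, no dye effect, arrays taken as independent, rat values first and then limma, array weights, all signs turned, and each rat left out in turn. Chosen after seeing the data were the array median as a covariate, leaving out or turning the 2 arrays named above, keeping the ceiling values, and the part of the loop as a term. A filter on dim spots could not be run because the table holds no intensities, and for the same reason no intensity-dependent (loess) correction was made.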

Results

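Rat liver RNA from 4 groups was compared: endophyte-free (E-) or endophyte-infected (E+) fescue seed in the diet, at thermoneutrality (TN) or under heat (HS), with 5 rats per group and 3 arrays per rat. Of 22367 genes and unnamed probes tested, 101 passed an adjusted p of 0.05 for diet averaged over both temperatures, and 0 passed it for heat, for the interaction or for either effect in a single setting. All fold changes are log2, with standard errors, and all signs are conditional on a ratio of Cy5 over Cy3. The arrays differed in their balance of the 2 dyes. Over 28 arrays, the score on the first principal component, which held 25.7% of the variance, went with the median log2 ratio of the array. Here Pearson's r was 0.763 and Spearman's coefficient 0.781, each with a two-sided permutation p = 1e-05, the smallest that 100000 permutations can give. This was the only such relation computed, and r was 0.705 without the 2 arrays whose medians lay farthest from the rest. Another 2 arrays, both carrying E+HS rat 35, correlated below 0 on average with the others and were kept out of this relation. They lay -3.27 and -2.55 residual SD from its line. The permutations treat arrays as exchangeable, but arrays share rats, so these p values are approximate.

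**Figure D1:**
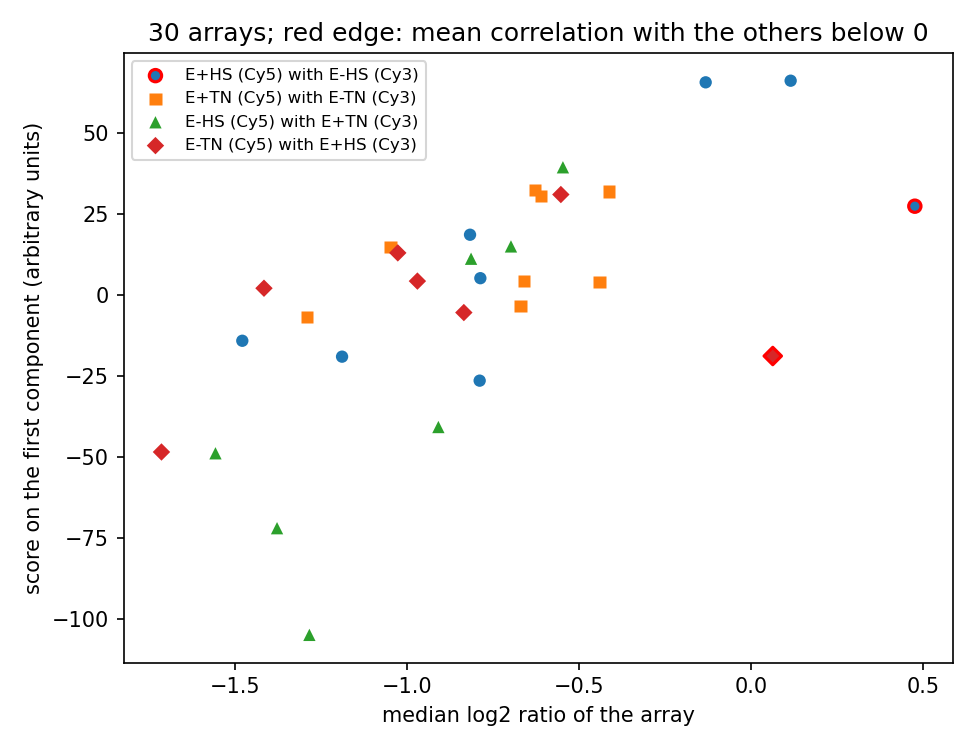
Median log2 ratio of each of the 30 arrays against its score on the first principal component, with 1 symbol per pairing of groups. Red edges mark the 2 arrays whose mean correlation with the others was below 0.

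With endophyte-infected seed, averaged over both temperatures, 97 genes rose and 4 fell (4 and 97 if the ratio is Cy3 over Cy5). Among the largest rises were Tmem161a, a membrane protein (0.73 ± 0.145, a fold of 1.66, adjusted p = 0.0177, 9 of 10 rats), and Klc3, a kinesin light chain (0.68 ± 0.12, adjusted p = 0.0103, 9 of 10). Klc3 averaged -0.18 ± 0.39 (SD, n = 5) in E-TN, 0.52 ± 0.43 in E+TN, -0.51 ± 0.53 in E-HS and 0.17 ± 0.47 in E+HS. Acot1, an acyl-CoA thioesterase that frees fatty acids from coenzyme A, fell most (-0.75 ± 0.15, adjusted p = 0.0229, 9 of 10 rats). Its group means were 0.21 ± 0.53, -0.66 ± 0.39, 0.54 ± 0.36 and -0.09 ± 0.86 in the same order. The odorant receptor Olfr25 (0.62 ± 0.12, adjusted p = 0.0131, 9 of 10) and the GABA transporter Slc6a11 (0.57 ± 0.11, adjusted p = 0.0131, 10 of 10) rose as well. So did Cxxc1, which binds CpG sites in a histone methyltransferase complex (0.58 ± 0.125, adjusted p = 0.0287, 10 of 10). Further rises were those of the retinol dehydrogenase Rdh14 (0.56 ± 0.12, adjusted p = 0.0273, 9 of 10), the RNA-binding Rbm12 (0.55 ± 0.10, adjusted p = 0.0131, 9 of 10) and the axon guidance ligand Slit1 (0.55 ± 0.12, adjusted p = 0.036, 8 of 10). Nt5el (-0.70 ± 0.16, adjusted p = 0.0409, 7 of 10) and Astn1, which acts in neuronal migration (-0.63 ± 0.15, adjusted p = 0.0491, 10 of 10), fell. The table holds no intensities, so whether these genes gave signal above background in liver could not be examined. Of the 101, 77 higher and 3 lower have a symbol and 20 higher and 1 lower have none. All 101 had the same sign at both temperatures, which their selection on the average of both makes likely. Their sizes ran from 0.245 to 0.751 with a median of 0.408. For Tmem161a, the E+ rats of the first part of the loop lay between 0.896 and 1.14. Those of the second part lay between -0.505 and -0.114. Only 2 arrays join the parts, so this offset rests on them. The rat counts and the SDs include such an offset wherever a gene has one.

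**Figure D2:**
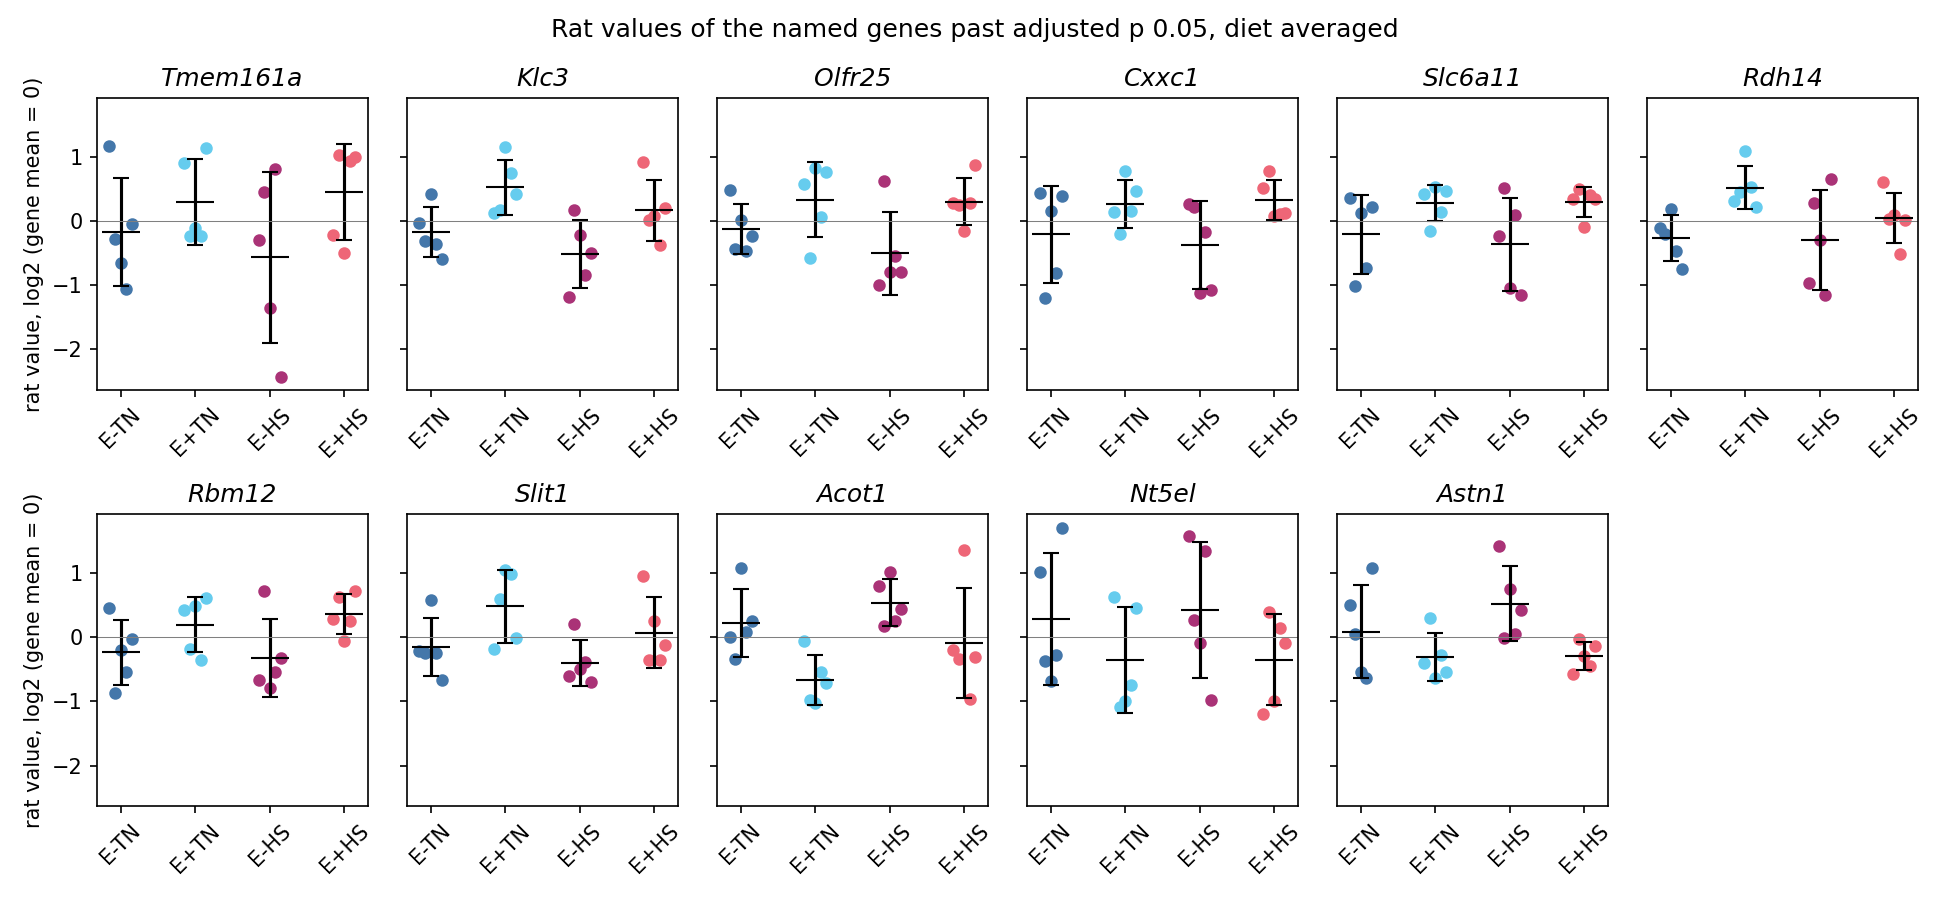
Values of the 20 rats for the 11 genes with the largest changes with diet past the threshold, 5 rats per group, log2 with the mean of each gene set to 0. Black lines are group means and bars are SD.

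Among the genes of the immune and repair lists, Cd14, a co-receptor for bacterial lipopolysaccharide, rose with endophyte-infected seed (0.43 ± 0.077, adjusted p = 0.0131, 10 of 10 rats). It was the only one of 51 acute phase genes to pass over all genes and also when adjusted over the list alone (17 higher, 34 lower). In the macrophage list (23 measured, 11 higher and 12 lower), Cd14 passed over all genes, and Cd14 and Lyz2 passed adjusted over the list alone. Xrcc1, which acts in DNA strand-break repair, rose (0.37 ± 0.081, adjusted p = 0.0311, 10 of 10). It was the only 1 of 44 apoptosis and DNA damage genes to pass over all genes (19 higher, 25 lower), against 3 adjusted over the list alone, with Bcl2l1 and Gadd45a. Neither of its 2 probes passed alone (0.36, adjusted p = 0.101, and 0.38, adjusted p = 0.111). Complement and coagulation (42 measured, 12 higher, 30 lower) and lymphocyte and neutrophil markers (26 measured, 17 higher, 9 lower) had no member past the threshold in either count. The clotting factor F7 lay at 0.29 ± 0.089 (adjusted p = 0.119, 9 of 10) and the neutrophil protease Elane at 0.23 ± 0.082 (adjusted p = 0.156, 7 of 10).

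Among stress lists, Syvn1, a ubiquitin ligase that removes misfolded proteins from the endoplasmic reticulum, rose with endophyte-infected seed (0.42 ± 0.095, adjusted p = 0.0387, 9 of 10 rats). It was the only 1 of 43 endoplasmic reticulum stress genes to pass, over all genes and adjusted over the list alone (17 higher, 26 lower). Of its 2 probes 1 passed (0.76, adjusted p = 0.0132) and the other did not (0.080, adjusted p = 0.684). Cytosolic chaperones had 0 of 55 past the threshold in both counts (26 higher, 29 lower). Fkbp5, a glucocorticoid-induced co-chaperone, had the smallest p (0.29 ± 0.098, adjusted p = 0.147, 6 of 10), Hspa1a lay at -0.051, Hspa1b at 0.25, Hspa8 at -0.026 and Hsp90aa1 at 0.042. The endoplasmic reticulum chaperone Hspa5 lay at -0.14. Of 45 antioxidant genes (25 higher, 20 lower), 0 passed over all genes and 1, the kinase Oxsr1, adjusted over the list alone (0.58 ± 0.16, adjusted p = 0.0899 over all genes, 10 of 10). Hmox1 lay at 0.067, Cat at 0.091 and Gpx1 at -0.11. Of 48 proteasome genes (19 higher, 29 lower), 0 passed over all genes and 2, Psmb9 (0.34 ± 0.089, adjusted p = 0.0721, 9 of 10) and Psmd14, adjusted over the list alone. Ribosomal proteins had 0 of 65 in both counts (18 higher, 47 lower; Rpsa at 0.25 ± 0.080, adjusted p = 0.127). The cell cycle had 0 of 43 (25 higher, 18 lower; Cdkn1b at 0.24 ± 0.067, adjusted p = 0.0945, 10 of 10).

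Among metabolic lists, the 75 measured oxidative phosphorylation genes lay lower as a group with endophyte-infected seed (58 lower, 17 higher, median -0.051, adjusted p = 0.0464 over 30 lists), as did hepatocyte markers (median -0.12, adjusted p = 0.0464). The adjusted p was 0.914 with an estimated correlation for both lists, each also lost in 11 of 20 fits without 1 rat, and 0 members passed in either count. The ATP synthase subunit Atp5pb lay at -0.33 ± 0.11 (adjusted p = 0.145, 8 of 10). Fatty acid oxidation had 1 of 57 past the threshold in both counts, Acot1 (22 higher, 35 lower), with the mitochondrial entry enzyme Cpt1a at -0.24. Fatty acid and triglyceride synthesis (37 measured, 17 higher, 20 lower), cholesterol synthesis (28, with 13 and 15) and bile acid synthesis (24, with 14 and 10) had 0 in both counts. In these 3 lists, Scd, a fatty acid desaturase, lay at -1.25 ± 0.40 (adjusted p = 0.133, 8 of 10), Fasn at -0.27 ± 0.195, Lpin1 at 0.20 ± 0.077 and Acox2 at 0.26 ± 0.098. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay at 0.27 ± 0.14 (adjusted p = 0.312). Of 43 genes of glucose production and glycogen (17 higher, 26 lower), 0 passed over all genes and 1, the transaminase Got1, adjusted over the list alone (0.40 ± 0.11, adjusted p = 0.0886, 10 of 10). Pck1 lay at -0.23. Amino acid breakdown and the urea cycle, where Got1 also had the smallest p, had 0 of 59 in both counts (20 higher, 39 lower).

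Among xenobiotic and hormone lists, 0 of 39 phase I genes (18 higher, 21 lower), 0 of 40 conjugation genes (18 higher, 22 lower) and 0 of 32 transporters (9 higher, 23 lower) passed in either count. Their members with the smallest p were the nuclear receptor Nr1i3 (0.29 ± 0.094, adjusted p = 0.138, 8 of 10 rats), the bilirubin transferase Ugt1a1 (0.26 ± 0.099, adjusted p = 0.187, 6 of 10) and the sterol transporter Abcg5 (0.38 ± 0.11, adjusted p = 0.113, 6 of 10). Cyp1a2 lay at -0.13. Growth hormone and sex-dependent genes had 0 of 28 in both counts (13 higher, 15 lower), with Igfbp2 at 0.225 ± 0.069 (adjusted p = 0.12, 9 of 10) and Igf1 at -0.16. Of 21 thyroid response genes (11 higher, 10 lower), 0 passed over all genes and 3, Rxrb, Dio3 (0.37 ± 0.11, adjusted p = 0.104, 8 of 10) and Bcl3, adjusted over the list alone. Of 19 clock genes (12 higher, 7 lower), 0 passed over all genes and 1, the core activator Bmal1, adjusted over the list alone (-0.26 ± 0.066, adjusted p = 0.0697, 9 of 10).

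Among cell type markers, the 21 measured hepatocyte markers lay lower as a group with endophyte-infected seed (18 lower, 3 higher, median -0.12, adjusted p = 0.0464). The adjusted p was 0.914 with an estimated correlation, and 0 members passed in either count. G6pc1, which releases glucose, lay at -0.415 ± 0.18 (adjusted p = 0.234, 7 of 10) and Alb at -0.11. Of 18 biliary markers (5 higher, 13 lower) and 25 markers of adipose, pancreas and muscle (11 higher, 14 lower), 0 passed over all genes. Adjusted over the list alone, the tight junction gene Cldn4 passed in the first (0.295 ± 0.078, adjusted p = 0.0807, 9 of 10) and 2 pancreatic enzymes, Cel and Ctrb1 (0.26 ± 0.075, adjusted p = 0.106, 8 of 10), in the second. Stellate (29 measured, 17 higher, 12 lower), endothelial (28, with 20 and 8) and red blood cell markers (12, with 7 and 5) had 0 in both counts. Thy1 lay at 0.17 ± 0.063, Selp at 0.55 ± 0.17 (adjusted p = 0.123, 9 of 10) and Slc4a1 at 0.13 ± 0.076. The adjusted p of the other 28 lists lay between 0.388 and 0.951. In 5 of these the median, the mean and the test differ in sign, namely conjugation, the cell cycle, apoptosis, macrophages and red blood cells.

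**Figure D3:**
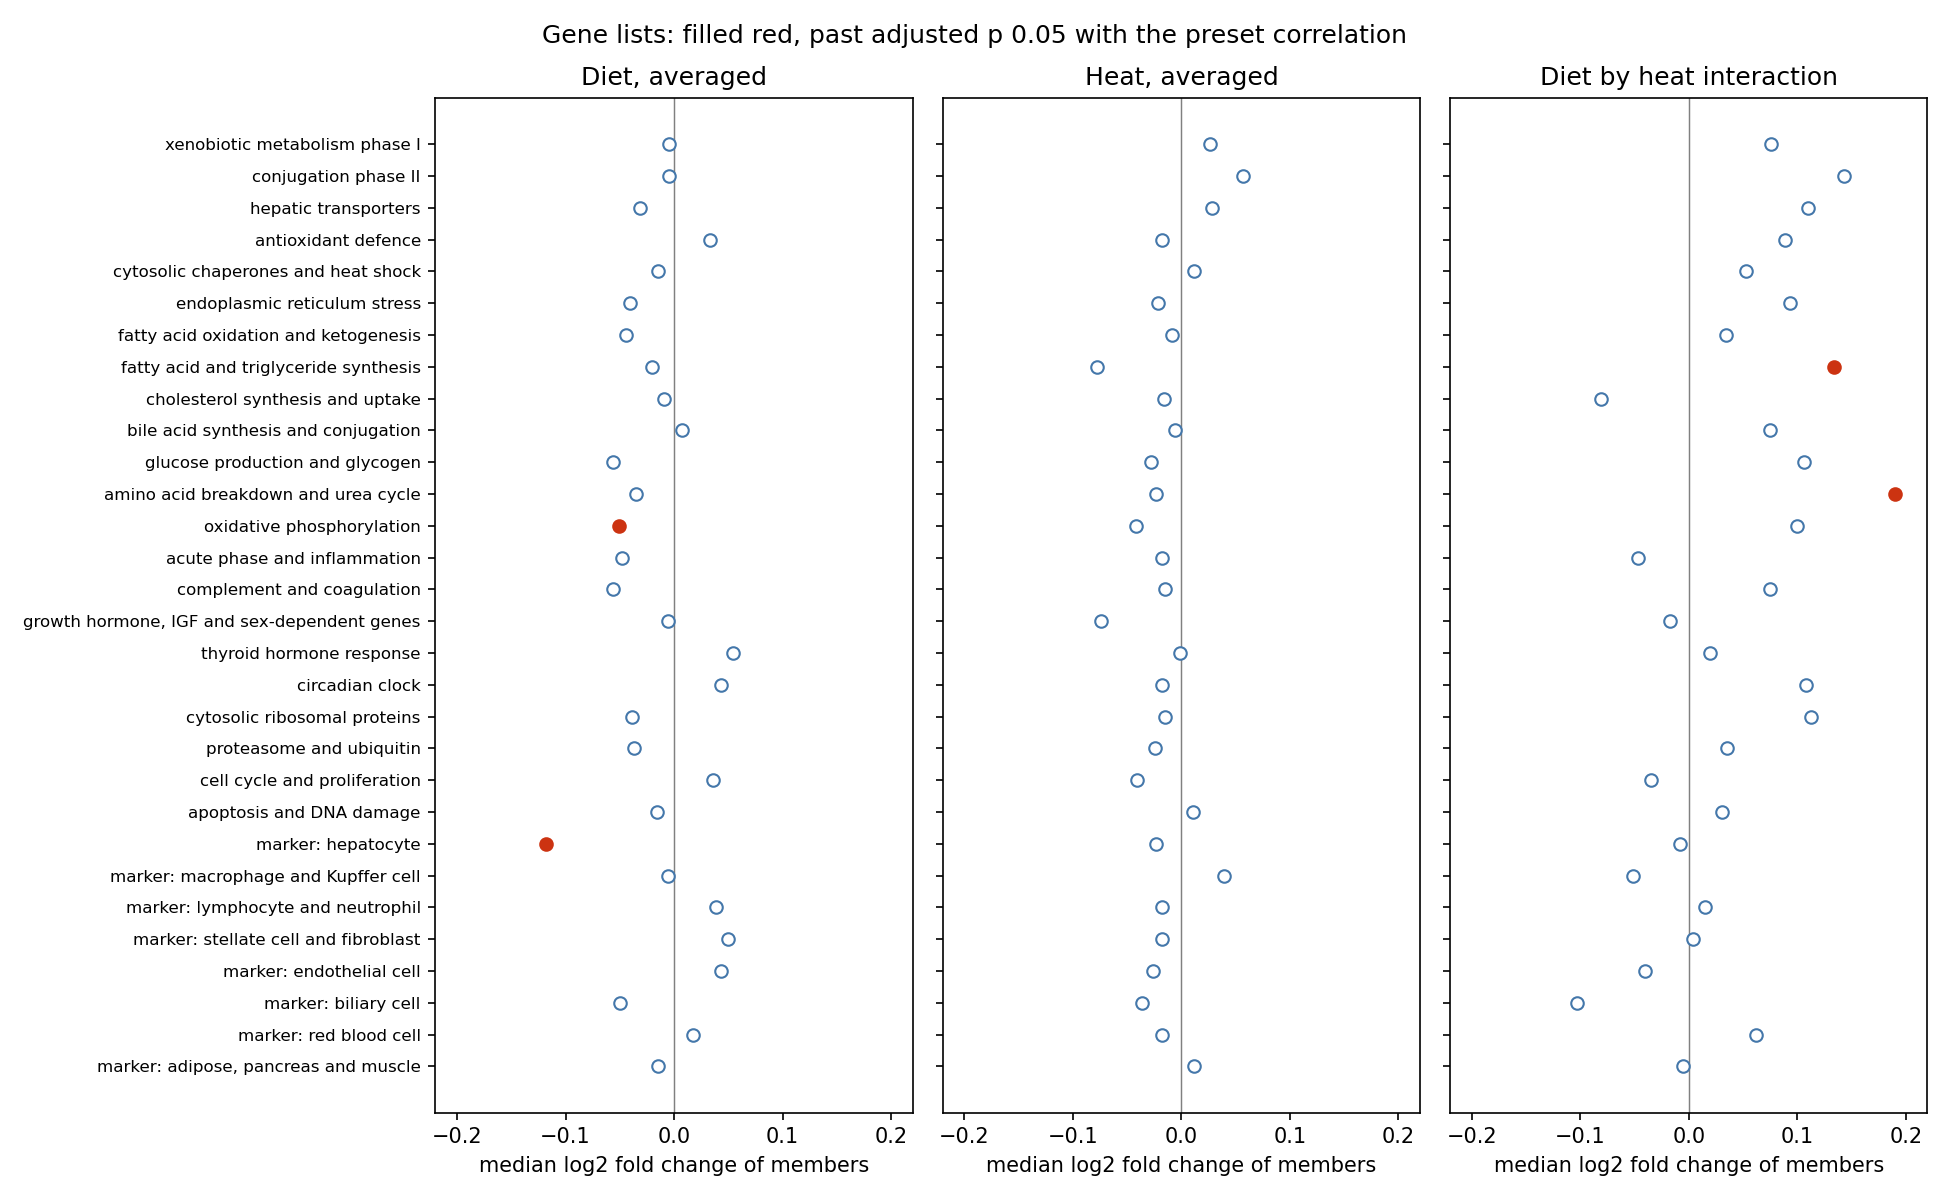
Median log2 fold change of the measured members of the 30 gene lists for diet averaged, heat averaged and the interaction. Filled red points passed an adjusted p of 0.05 with the preset correlation; with an estimated correlation, 0 lists passed.

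In limma over all 22367 genes, 3783 (16.9%) had an unadjusted p under 0.05 for the diet average, and the smallest adjusted p was 0.0102. Chance alone would on average put a share of 0.05 of the genes there. With rat values first and then limma, 0 genes passed and 223 had an unadjusted p under 0.05. In all 7 comparisons this fit put fewer genes there than that share, so it may be too strict. Its 0 calls therefore do not show that a change is absent. In the main fit, 0 genes passed for the diet average with the sign of the 2 arrays named above turned, or without any 1 of rats 24, 32, 37, 28, 20 and 11. The count was 7 without those 2 arrays and 746 without rat 23.

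At thermoneutrality, the genes with the smallest p for diet were Arhgef19 (-0.51 ± 0.11), Rdh14 (0.83 ± 0.19), the CREB coactivator Crtc1 (0.595 ± 0.14), Bzw1 (-0.77 ± 0.19) and the orphan receptor Gpr162 (0.42 ± 0.105), each in 5 of 5 rats with an adjusted p of 0.941. As groups, amino acid breakdown and the urea cycle (47 of 59 lower, median -0.10, adjusted p = 0.00436), oxidative phosphorylation (57 of 75 lower, -0.088, adjusted p = 0.0213) and ribosomal proteins (51 of 65 lower, -0.10, adjusted p = 0.0305) lay lower in E+TN than in E-TN. Each had an adjusted p of 0.891 with an estimated correlation, and 0 of their members passed in either count. Adjusted over the list alone, Cd14 passed among the macrophage markers. In limma, 0 genes passed the threshold and 1156 (5.17%) had an unadjusted p under 0.05, close to the share of 0.05 that chance gives on average. With rat values first and then limma it was also 0, with 101 under 0.05.

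Under heat, the genes with the smallest p for diet were the zinc finger gene Zfp473 (0.78 ± 0.16), Fam228b (0.605 ± 0.13), the ubiquitin ligase adaptor Klhl21 (0.365 ± 0.082) and Zfp574 (-0.67 ± 0.15), each in 5 of 5 rats. Thap4 lay at -0.74 ± 0.17 (4 of 5), and all 5 genes had an adjusted p of 0.253. Acot1 lay at -0.61 here and at -0.89 at thermoneutrality, Tmem161a at 0.98 and 0.48, Klc3 at 0.61 and 0.75, and Rdh14 at 0.29 and 0.83. Hepatocyte markers had the smallest p of the lists with 15 of 21 lower (median -0.12, adjusted p = 0.569), and 0 lists passed. In limma, 0 genes passed the threshold and 2579 (11.5%) had an unadjusted p under 0.05. From rat values first and then limma it was also 0, with 295 under 0.05.

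Averaged over both diets, heat had its smallest p values in Aph1c, a gamma-secretase subunit (0.42 ± 0.091, 10 of 10 rats), Gcsam, a lymphocyte signalling adaptor (-0.95 ± 0.22, 10 of 10) and Sectm1a (0.38 ± 0.090, 10 of 10). The glycerate kinase Glyctk (0.46 ± 0.11, 9 of 10) and the pheromone receptor Vmn1r25 (0.78 ± 0.19, 8 of 10) followed, and all 5 had an adjusted p of 0.774. The list of 55 chaperone genes did not pass (31 higher, 24 lower, median 0.012, adjusted p = 0.834), and 0 members passed in either count. The inducible heat shock genes Hspa1a and Hspa1b lay at 0.015 ± 0.12 (adjusted p = 0.985) and 0.26 ± 0.19 (adjusted p = 0.797). The 2 probes of Hspa1b gave 0.74 and -0.19. Hspa8 lay at -0.047 ± 0.24, Hsp90aa1 at 0.085 ± 0.17 and Hspa5 at -0.14 ± 0.17. The small heat shock gene Hspb1 lay at 0.39 ± 0.16 (adjusted p = 0.774, 8 of 10).

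In metabolism, the lists with the smallest p for heat were fatty acid and triglyceride synthesis (22 of 37 lower, median -0.078) and oxidative phosphorylation (51 of 75 lower, -0.042), each with an adjusted p of 0.172. Named members there and in related lists were the lipogenic regulator Mid1ip1 (-0.32 ± 0.15), Fasn (-0.28 ± 0.27), Cpt1a (-0.45 ± 0.24, 8 of 10), Acot12 (0.39 ± 0.15, with probes at 0.88 and -0.10), Acat2 (-0.14 ± 0.090), Nr0b2 (0.51 ± 0.23) and Atp5f1b (-0.25 ± 0.093, 10 of 10). In glucose and amino acid metabolism, the glucose 6-phosphate transporter Slc37a4 lay at -0.46 ± 0.14 (8 of 10), Pck1 at -0.034 and the tryptophan pathway gene Kynu at 0.59 ± 0.17 (7 of 10). In xenobiotic and antioxidant metabolism, Adh4 lay at 0.54 ± 0.18, Ugt1a9 at 0.25 ± 0.088, Abcc6 at -0.30 ± 0.15 and Selenop at -0.30 ± 0.16. Of the panel, Cyp1a2 lay at -0.16, Cyp7a1 at 0.14, Cat at -0.070, Gpx1 at 0.099 and Hmox1 at 0.059. Of hormone and clock genes, Esr1 lay at -0.50 ± 0.20 and Igf1 at -0.068. Gpd2, which thyroid hormone induces, lay at -0.73 ± 0.22 (9 of 10), and the clock repressor Nr1d1 at -0.59 ± 0.16 (8 of 10). Nr1d1 was the only member of any list to pass adjusted over the list alone, and 0 passed over all genes.

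Among the other lists under heat, immune members with the smallest p were the chemokine Cxcl1 (0.36 ± 0.13, 8 of 10), F13a1 (0.45 ± 0.22), the protease Ctss (0.81 ± 0.28, 8 of 10) and the T cell marker Cd8a (0.92 ± 0.27, 9 of 10). In protein turnover and cell division these were Derl2 (-0.32 ± 0.13), Rpl37 (0.31 ± 0.13, with probes at -0.052 and 0.745), Psmf1 (0.18 ± 0.095), Mcm5 (-0.38 ± 0.16) and Xiap (0.65 ± 0.24). Markers of other cells gave Col3a1 at -0.30 ± 0.17, Tek at 0.20 ± 0.11, Aqp1 at 0.35 ± 0.16, Car2 at -0.40 ± 0.20 and the pancreatic Cpb1 at 0.29 ± 0.10 (10 of 10). For hepatocytes, Hnf4a lay at -0.16 ± 0.13 and Alb at 0.024. The adjusted p of the members with the smallest p of their list was 0.774 but for Acat2 (0.779) and Hnf4a (0.814). In the panel it was 0.774 for Cpt1a, 0.843 for Fasn, 0.982 for Pck1, 0.95 for Igf1 and 0.987 for Alb. In limma, 0 genes passed the threshold for heat and 1394 (6.23%) had an unadjusted p under 0.05. Rat values first and then limma gave 0 as well, with 557 under 0.05. In the simulation with independent genes, the heat average recovered 33 of 100 genes changed by 0.5 and 80 of 100 changed by 1. Heat changes of 0.5 could thus have been missed, but whether this explains the absence of calls was not tested.

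On endophyte-free diet, the genes with the smallest p for heat were the chaperone cofactor Dnajc17 (-0.69 ± 0.16), the odorant receptor Olr59 (-0.725 ± 0.175) and Gt4-1 (-0.59 ± 0.15), each in 5 of 5 rats. H2-M10.4 (-1.05 ± 0.27) and Uhrf1bp1 (-0.82 ± 0.22) followed, each in 4 of 5, and all 5 genes had an adjusted p of 0.996. Of the lists, 5 lay lower as groups in E-HS than in E-TN. These were fatty acid and triglyceride synthesis (27 of 37 lower, median -0.13, adjusted p = 0.00122), amino acid breakdown and the urea cycle (47 of 59, -0.13, adjusted p = 0.00122) and oxidative phosphorylation (52 of 75, -0.083, adjusted p = 0.0408). The others were endoplasmic reticulum stress (29 of 43, -0.086, adjusted p = 0.0458) and ribosomal proteins (52 of 65, -0.078, adjusted p = 0.0458). Each had an adjusted p of 0.978 with an estimated correlation. The amino acid, oxidative phosphorylation and ribosomal lists also lay lower in E+TN than in E-TN. Both comparisons use the same E-TN rats, so these results are not independent. List calls of single comparisons were not repeated with rats left out or regrouped. Adjusted over the list alone, only the pancreatic enzyme Cpa1, in the list of neighbouring tissue, passed. In limma, 0 genes passed the threshold and 836 (3.74%) had an unadjusted p under 0.05, below the share of 0.05 that chance gives on average. With rat values first and then limma it was also 0, with 190 under 0.05.

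On endophyte-infected diet, the genes with the smallest p for heat were Glyctk (0.78 ± 0.15, adjusted p = 0.328), Sectm1a (0.58 ± 0.12, adjusted p = 0.64) and Acsbg3 (-0.54 ± 0.12, adjusted p = 0.64). The transcription factor Klf11 (-0.69 ± 0.16, adjusted p = 0.671) and the cyclic nucleotide-gated channel Cnga3 (-0.60 ± 0.14, adjusted p = 0.671) followed, and each of the 5 showed its direction in 5 of 5 rats. The amino acid list had 39 of 59 members higher (median 0.070, adjusted p = 0.94) and fatty acid and triglyceride synthesis 20 of 37 higher (0.022, adjusted p = 0.94; the mean was 0 and the test pointed down). Of the lists, 0 passed, and adjusted over the list alone Cd8a passed among the lymphocyte markers. In limma, 0 genes passed the threshold and 1322 (5.91%) had an unadjusted p under 0.05. From rat values first and then limma it was also 0, with 552 under 0.05. The count was 2 with array weights, 1 with the array median as a covariate, and 19 without rat 15.

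For the interaction, genes of amino acid breakdown and the urea cycle lay on the higher side as a group (48 of 59, median 0.19, adjusted p = 0.00507), and so did fatty acid and triglyceride synthesis (28 of 37, median 0.13, adjusted p = 0.0493). Both had an adjusted p of 0.988 with an estimated correlation, and 0 members of any list passed in either count. Both lists also lay lower in E-HS than in E-TN. The same E-TN rats enter that comparison and the interaction, so these results are not independent. The amino acid genes had a median of -0.10 with endophyte-infected seed at thermoneutrality and 0.051 under heat (36 of 59 higher, adjusted p = 0.698). The lipid genes had -0.083 at thermoneutrality (25 of 37 lower, adjusted p = 0.0683) and 0.094 under heat (24 of 37 higher, adjusted p = 0.698). Gldc, which breaks down glycine, had an interaction of 0.675 ± 0.22, with a diet effect of -0.30 at thermoneutrality and 0.375 under heat. Agpat1, an enzyme of triglyceride synthesis, had 0.62 ± 0.31, with -0.24 and 0.39. The next lists were conjugation (28 of 40 higher, 0.14) and ribosomal proteins (55 of 65 higher, 0.11), each with an adjusted p of 0.176, and biliary markers (12 of 18 lower, -0.10, adjusted p = 0.237).

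The smallest p values of single genes for the interaction belonged to Arhgef19 (0.73 ± 0.17), Olr59 (0.94 ± 0.24), the mitochondrial dicarboxylate carrier Slc25a10 (0.48 ± 0.12), Phactr1 (-0.84 ± 0.23) and Dnai4 (0.79 ± 0.22), all with an adjusted p of 1. In Arhgef19 the diet effect was -0.51 at thermoneutrality and 0.22 under heat, and in Slc25a10 -0.24 and 0.24. Large uncalled values were those of Cyp2c12, a cytochrome of female rat liver (-2.25 ± 0.76), the chaperone Hspa4l (-2.04 ± 0.74), Cox15 (-1.33 ± 0.565), the glutaredoxin Glrx (1.34 ± 0.73), Rplp0 (1.11 ± 0.51) and Hamp, which encodes the iron hormone hepcidin (-1.08 ± 0.38). Other metabolic members of the lists lay at 0.30 ± 0.18 (Gsta3), -0.55 ± 0.23 (Slc13a3), 0.63 ± 0.34 (Eci2), 0.375 ± 0.23 (Scarb1), -0.76 ± 0.335 (Slc27a5), 0.36 ± 0.17 (Irs1), 0.63 ± 0.23 (Crym) and -0.72 ± 0.40 (Tat). For stress, clock and division these were Ddit3 (0.37 ± 0.17), Dbp (-0.64 ± 0.44), Psmf1 (0.29 ± 0.18), Racgap1 (-0.68 ± 0.26) and Btg1 (0.43 ± 0.23). For immune genes and markers these were Masp2 (-0.44 ± 0.22), Cd5l (-0.76 ± 0.425), Ccr7 (-0.37 ± 0.17), Lox (0.65 ± 0.26), Ptprb (-0.415 ± 0.19), Tff3 (-0.48 ± 0.225), Gata1 (-0.55 ± 0.26) and Cpa1 (0.80 ± 0.32). Of the panel, Hspa1a lay at -0.32 ± 0.22, Cat at 0.38 ± 0.27, Fasn at 0.44 ± 0.51, Igf1 at -0.30 ± 0.31 and Pck1 at -0.29 ± 0.38. The values of Hspa1b, Hspa8, Hsp90aa1, Hspa5, Hmox1, Cyp1a2, Cyp7a1, Gpx1, Cpt1a and Alb lay between -0.23 and 0.20. In limma, 0 genes passed the threshold for the interaction and 785 (3.51%) had an unadjusted p under 0.05, below the share of 0.05 that chance gives on average. Rat values first and then limma gave 0 as well, with 180 under 0.05. The simulation with independent genes recovered 4 of 100 genes with an interaction of 0.5 and 42 of 100 with an interaction of 1. Interactions of these sizes could thus have been missed, but whether this explains the absence of calls was not tested.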

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

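The tests of the diet changes by the array median and by the 2 arrays, and both tests of the 2 arrays, were chosen only after the result was seen, while the splits were predicted before it, with the genes they use widened after a first run and the splits within parts of the loop added last. In E-HS, rat 15 lay far above its group for Olfr25 (0.623, nearest -0.548, lowest -0.991), and in E+HS rat 23 lay far below its group for Slc6a11 (-0.101, nearest 0.339, highest 0.501). Missing spots were far more frequent on replicate 5 of the E+TN with E-TN arrays (1359, nearest 869, lowest 442) and on replicate 7 of the E-TN with E+HS arrays (2988, nearest 1020, lowest 482). Of 72 groups examined, 4 held such a value, and chance marks about 1 in 20. The diet effect differed between temperatures by a test of the difference for fatty acid and triglyceride synthesis (adjusted p = 0.0493) and for amino acid breakdown and the urea cycle (adjusted p = 0.00507). Both had an adjusted p = 0.988 with an estimated correlation, and the first was lost in 9 and the second in 4 of 20 fits with a rat left out. As many lists were called for the interaction in 60 of 100 splits of the rats, so chance is not excluded.

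The changes with endophyte-infected seed were mostly rises (97 of 101), or mostly falls (97 of 101) if the ratio is Cy3 over Cy5. The array medians averaged -0.720 and -0.574 where the E+ rat was in Cy5, and -1.026 and -0.921 where the E- rat was. With the array median as a covariate, the median size of the called genes was 0.995 times itself (0.408 and 0.406). There 58 genes passed, all higher, 52 of them among the 101. This argues against a linear effect of the array median. A dye effect that depends on spot intensity could not be examined, since the table holds no intensities. For the 2 arrays that run against the others no test decides. Without them the size was 0.963 times itself (0.408 and 0.393, median standard error 0.0862 and 0.0895), but the count fell to 7. With their sign turned the count was 0, while the median size of the 101 genes was 0.337 and all kept their sign. Of 100 splits of the rats by diet within temperature, the real one included, 2 gave at least the real 101 called genes. So did 2 of 100 splits that kept to the parts of the loop of arrays. Both shares lie under the bound of 5 in 100 set beforehand, but they do not exclude chance. Every array sets an E+ rat beside an E- rat, which the other splits do not keep, and only 100 splits were drawn for each. The highest other splits gave 1030 and 356 genes, several times the real count, which points to a structure of the samples whose kind was not tested, and at an unadjusted p under 0.05 as many as 9 and 3 of the 100 reached the real count (3783, highest other 5527 and 4968).

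For the other comparisons, splits were counted at an unadjusted p under 0.05, again with 100 each and the real one included. The splits with as many genes numbered 12 for diet at thermoneutrality (real 1156, highest other 2279), 23 for diet under heat (2579, 7822) and 64 for heat on endophyte-free diet (836, 5461). They numbered 9 for heat on endophyte-infected diet (1322, 2555), 16 for heat averaged (1394, 3603) and 61 for the interaction (785, 7868). For diet under heat, heat on endophyte-free diet and the interaction the highest other count was several times the real one, which points to a structure of the samples. For the interaction, splits within the parts of the loop called at most 75 genes against 3824 over all splits, and 50 of 100 reached the real count at an unadjusted p under 0.05 (highest other 5335). For heat averaged these were 17 (highest other 4659). As many lists as the 2 of the diet average were called in 50 splits (highest other 19), and as many as the 2 of the interaction in 60 (highest other 20). Chance cannot be excluded for any of these counts of genes or lists.

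The 2 arrays with rat 35 that correlate below 0 with the others could hold their ratio the other way round. Each gene's dye effect and slope on the array median, fitted on the other arrays, were removed first. Their correlations with arrays that share a rat, signed by the dye of that rat, then averaged -0.114 over 6 pairs. The single values were mixed (-0.063, 0.0809, -0.248, 0.199, -0.332 and -0.318). The 53 other pairs averaged 0.0276 (SD 0.17), and 1.06% of 378 sets of 2 other arrays lay as low. The 2 arrays lay -3.27 and -2.55 residual SD from the line of score against array median, which was fitted on the other arrays. This cannot exclude the balance of the dyes as their cause. They were picked because they run against the others, and the median of 1 of them (0.477) lies above the highest in the fit (0.116). The bound of the first test was set after its first value was seen, and no biological explanation was tested. The third array of rat 35, with rat 30, runs with the others (mean r = 0.186), which argues against a cause in that rat alone.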

How the results depend on the processing

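The diet average had 101 called genes, 97 higher and 4 lower, or 4 higher and 97 lower with all signs turned. It gave 27 (27 higher) without centring and 154 (152 higher) with only genes measured on all arrays. It gave 313 (277 higher) with arrays taken as independent and 160 (144 higher) with array weights. With rat values first, a fit that may be too strict, it gave 0. Among alternatives chosen after seeing the data, it gave 58 (58 higher) with the array median as a covariate, 7 (7 higher) without the 2 arrays with rat 35 that run against the others, and 0 with their sign turned. It stayed between 82 and 143 with scaled spread, the other filter, each probe alone, no dye effect, ceiling values kept and, also chosen after seeing the data, the part of the loop as a term (120, 116 higher). All 101 genes kept their sign in each of these, or all 98 that were tested where only genes measured on all arrays were used. Their selection in the same data makes this likely. With each rat left out in turn the count ran from 0 to 746: 0 without rats 24, 32, 37, 28, 20 or 11, 5 without 35, 6 without 19, 22 without 12, 26 without 30, 33 without 222, 45 without 25, 53 without 31, 60 without 17, 66 without 16, 244 without 15 and 746 (629 higher) without 23. Heat on endophyte-infected diet had 0 called genes, but 2 with array weights, 1 with the covariate and from 0 to 19 with rats left out (19, 18 of them higher, without rat 15); all other comparisons stayed at 0. The count at an unadjusted p under 0.05 moved too. For heat averaged (1394) it ran from 531 without centring to 2438 with the sign of the 2 arrays turned, was 695 with the part of the loop as a term, and was 4024 without rat 15 and 898 without rat 28. For heat on endophyte-infected diet (1322) it ran from 552 with rat values first to 2824 with array weights, was 716 with the part of the loop as a term, and was 3844 without rat 15, 662 without 24 and 740 without 30.

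For the averaged effects and the interaction together, 4 lists were called. The number was 9 with scaled spread, 2 with genes measured on all arrays, 1 with each probe alone, 2 without a dye effect, 0 with rat values first, 14 with array weights, 1 with the covariate, 20 without the 2 arrays, 27 with their sign turned, 1 with ceiling values kept, 8 with the part of the loop as a term, where fatty acid synthesis no longer passed (adjusted p = 0.0514), 0 with an estimated correlation and 0 with fry (smallest p for the diet average 0.0181 one way and 0.0042 either way). With each rat left out it ran from 0 (rats 37 and 17) to 21 (24 and 35), with 1 without 31 or 32, 2 without 14, 19 or 30, and 10 without 29, 12 or 34. Without centring the median of all genes in the diet average was 0.161, against -0.00357 with it, and the medians of the 2 diet lists turned positive, 0.045 for hepatocytes and 0.112 for oxidative phosphorylation.

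With a rat left out, oxidative phosphorylation and hepatocyte markers in the diet average each failed in 11 of 20 fits (medians -0.089 to -0.014 and -0.167 to -0.071). In the interaction, fatty acid synthesis failed in 9 (0.062 to 0.248) and amino acid breakdown in 4 (0.082 to 0.264). Of single genes, Klc3 stayed past the threshold in 13 of 20, Tmem161a, Olfr25 and Cd14 in 12, Slc6a11 and Rbm12 in 11, Cxxc1 in 10, Rdh14 in 7, Acot1 and Xrcc1 in 6, Slit1 in 5, Nt5el and Syvn1 in 4 and Astn1 in 2. Of 158 values of named genes that did not pass, 14 changed sign without centring and from 0 to 11 in the other settings but the turn of all signs. A ratio of Cy3 over Cy5 would turn every sign: Tmem161a -0.733, Klc3 -0.681, Olfr25 -0.622, Cxxc1 -0.582, Slc6a11 -0.571, Rdh14 -0.562, Rbm12 -0.552, Slit1 -0.55, Cd14 -0.428, Syvn1 -0.422, Xrcc1 -0.371, Acot1 0.751, Nt5el 0.699 and Astn1 0.631, and the medians of oxidative phosphorylation 0.051, hepatocytes 0.118, fatty acid synthesis -0.134 and amino acid breakdown -0.19. For the results that changed, the cause was not tested, beyond fewer rats or genes in some. The fit uses the pairing of 2 rats on each array. Beyond this, no paired analysis was possible because no rat was in 2 groups and replicate numbers link no rats. The filter on dim spots was not run, and signal over background could not be examined, since no intensities were used.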

Other observations

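The tests of a clock shift, with and without 2 of its genes, and of the parts of the loop were chosen only after the result was seen, and the test with the covariate before. Other genes past the threshold for diet averaged over both temperatures, chosen after their values were seen, include Slc31a2, a copper transporter (0.50 ± 0.085), and Kremen1, a Dickkopf receptor that restrains Wnt signalling (0.39 ± 0.067). Besides Olfr25, the odorant receptors Olfr711 (0.415), Olfr552 (0.33) and Olfr411 (0.245) rose. Of genes of blood and immune cells, the interleukin receptors Il2rb (0.54) and Il27ra (0.29), the urokinase receptor Plaur (0.44) and the platelet integrin Itga2b (0.46) rose. Odorant receptors and these genes were not fixed as lists, so their number was not tested. Whether they gave signal above background could not be examined.

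Under heat, clock genes of opposite phase tended to opposite sides, as seen before any test. In the phase of Bmal1 (0.16), Cry1 lay at 0.48, Clock and Npas2 at 0.036 each and Nfil3 at -0.185. In the phase of Nr1d1 (-0.59) and Dbp (-0.69), Per3 lay at -0.36, Per2 at -0.30, Tef at -0.16, Per1 at 0.033 and Hlf at 0.20. None of them passed the threshold over all genes. A score per rat, the mean of the first 5 genes minus the mean of the other 7, averaged -0.05 ± 0.40 (SD, n = 5) in E-TN, -0.36 ± 0.58 in E+TN, 0.23 ± 0.39 in E-HS and 0.18 ± 0.28 in E+HS.

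A shift of the clock with heat was a hypothesis made from these values, which therefore cannot bear it out. The score was higher under heat by 0.404 (exact two-sided permutation p = 0.0457 over 63504 arrangements), with 9 of 10 heated rats above the mean of the unheated and 4 of 10 unheated rats above the mean of the heated, and without Nr1d1 and Dbp, which prompted it, by 0.239 (exact two-sided p = 0.131). All exact p values of the score treat the rats as exchangeable. Rats share arrays, so their scores are not independent and these p values are approximate. The score also differed between the parts of the loop of arrays. Its mean was 0.352 in the first, which has 6 heated rats, and -0.352 in the second, which has 4. Only 2 arrays join the parts, so this difference rests on them, and they include an array that runs against the others. Averaged within diet and part, the heat difference was 0.679 times itself (0.274, exact two-sided p = 0.0314 over 10000 arrangements; 0.056 in the first part and 0.49 in the second), and without the 2 genes 0.125 (exact two-sided p = 0.105), so the parts of the loop stay open as an explanation. As far as the array median measures it, the balance of the dyes does not account for the difference (0.94 times itself with the array median as a covariate, 0.374 and 0.351). In the gene fits, the heat difference was 0.374, and 0.348 without the 2 arrays that run against the others. Heat and the time of collection, which is not given in the sources used here, stay open and untested.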
